A study of Mus musculus with 9 samples.

How the data were processed

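Mouse fetal liver cells were freed of red cells, grown with cytokines, transduced with MSCV-based retroviruses and sorted for the virus's GFP, per the labels' protocols. RNA was extracted with Trizol LS, linearly amplified, labelled with biotin and hybridised to Affymetrix arrays. The authors deposited log2 values per probe set that had been made with RMA, per the submitters' processing notes, with no version given. RMA corrects the background, normalizes the arrays to each other and summarises each probe set, so real differences in total RNA between groups are removed and changes of weakly expressed genes are compressed. The deposited log2 values ran from 1.99 to 15.12. Scanner files were not used here.

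Arrays were put in 3 groups of 3 by the labels, and arrays of a group were numbered by a preparation mark that the descriptions share across groups. The meaning of the mark and of a coarser preparation code with 2 levels (6 and 3 arrays) is not stated. No pair of arrays was a duplicate: array correlations lay between 0.932 and 0.995, and at most 4.24% of values were identical. Probe sets were named with the platform annotation. Of the probe sets that are not Affymetrix controls, 34945 had 1 gene symbol, 932 had several and 9160 are unnamed here, and no gene was named from the latter kinds. Gene IDs of 34754 probe sets matched a gene table of assembly GRCm38.p6, which changed 0 symbols and was also used for which genes lie near each other.

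Tests ran in limma 3.58.1 under R 4.3.3 on the deposited log2 values, with a mean per group over all 9 arrays (6 residual degrees of freedom), empirical Bayes variances and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was tested if at least 3 arrays exceeded their own 40th percentile (4.40 to 4.53), which left 28000 probe sets, and the 64 Affymetrix control probe sets were left out. A gene was represented by its tested probe set with the highest mean, which gave 13916 genes. Calls are an adjusted p under 0.05. The contrasts were POU4F1 against the mean of both control groups, POU4F1 against each control group, and knockout against wild-type control. Where all arrays of a group lay at or below their 40th percentile, folds are lower bounds computed from the higher of the value and that percentile, and so, as chosen after seeing the data, where over 50% of a group's arrays did. Called here below background means below that percentile, since detection calls were not used here.

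Genes were named by a rule. For POU4F1 against both controls these are the 12 genes higher and 12 lower with the largest change among called genes whose groups did not overlap, and for the others the 5 higher and 5 lower, or, where none passed, the 3 with the smallest p on each side. Pou4f1 and, for each list described, the 4 members with the smallest p were added. In all, 23 gene lists (477 genes) for blood cell types, other fetal liver cells, stress and growth responses, sensory neurons and the leukaemia were written from general knowledge. Of these, 22 were tested with camera (inter-gene correlation 0.01, two-sided, adjusted over the 22 lists), beside camera with an estimated correlation and fry, and the list of sex-linked genes served as a check of the arrays. Members were counted over all probe sets and adjusted over the list alone. The design, the rule, the lists and most alternatives were fixed before the data were examined.

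The tests were checked on simulated data drawn with the spread of these arrays and 200 changed probe sets, where 4.55% to 6.99% of calls were false. A list shifted by 0.5 was recovered in 20 of 20 runs, with 1 of 420 tests of other lists called. Probe sets were drawn independently of each other, so these runs do not check camera on lists whose genes vary together. Nor do they check limma's share of false calls or of recovered changes where many probe sets vary together across arrays. Alternatives were other filters, quantile normalization, median centring, the preparation mark or code as a block, trended and robust variances, array weights, 1 probe set per gene, other thresholds, other sets of arrays, leaving out each array, other list tests and other probe sets per gene. Chosen after seeing the data were a covariate for RNA integrity, a second kind of array weights, the fit without the 2 outermost arrays and the fit within the first preparation. RNA integrity was taken as the Affymetrix Gapdh control's 5' minus 3' log2 value, which averaged -3.80 ± 1.94 (SD, n = 3) in wild-type controls, -3.34 ± 0.11 in knockout controls and -3.71 ± 0.84 with POU4F1.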

Results

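Gene expression was measured in cultured mouse fetal liver cells, a source of blood stem cells and progenitors, to find genes that respond to POU4F1. POU4F1 (BRN3A) is a POU-domain transcription factor best known from sensory neurons, and the series title links it to an acute myeloid leukaemia that carries a chromosome translocation. The 9 arrays fell into 3 groups of 3. The groups were wild-type cells with a control retrovirus, Pou4f1 knockout cells with the same control virus, and wild-type cells with a virus that carries Pou4f1. Array medians lay between 4.98 and 5.06 on the log2 scale, and 28000 probe sets passed the filter on low values. The labels do not say whether arrays of a group came from separate embryos, so the p-values measure the spread between these arrays, which may be partly technical. The number of arrays limits the precision of every value.

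Pou4f1 itself was measured by 2 probe sets, and neither rose above background on any array, the arrays of the Pou4f1 virus included. The first probe set averaged 3.34 ± 0.03 (SD, n = 3) in wild-type controls, 3.22 ± 0.22 in knockout controls and 3.41 ± 0.14 in the POU4F1 group. The other averaged 2.70 ± 0.03, 2.68 ± 0.03 and 2.77 ± 0.15 in the same order. All 9 arrays read both probe sets below their own 40th percentile, and limma's adjusted p for POU4F1 against both controls was 0.883 and 0.906 in a fit without the filter. Where these probe sets lie relative to the virus insert or to the deleted part of the gene is not given in the sources used here. The levels of Pou4f1 therefore check neither the virus nor the genotype label, and no fold is given.

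The first comparison asked which genes differ between cells with the POU4F1 virus and both kinds of control cells. Caveolin genes, Thy1 and several genes for membrane and signalling proteins rose by up to 40.6-fold, while the mast cell and basophil proteases Cma1 and Mcpt8 were among the genes that fell. Cav1, which encodes the main coat protein of caveolae, rose from 5.55 ± 0.31 (SD, n = 6) to 10.89 ± 0.22 (n = 3), a 40.6-fold change with an SE of 0.19 on the log2 scale (limma adjusted p = 1.48e-05). Cav2, its partner in caveolae, rose 11.4-fold (adjusted p = 0.00337), with 5 of the 6 control arrays above background. Thy1, a surface glycoprotein of T cells and neurons, rose 26.3-fold from 7.38 ± 0.51 to 12.09 ± 0.18 (adjusted p = 2.64e-04). Across all tested probe sets, 123 passed an adjusted p of 0.05, of which 99 were higher and 24 lower with POU4F1, and 2068 had an unadjusted p under 0.05. The 123 probe sets named 97 genes, 77 of them higher and 20 lower, and 9 had no single gene name.

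Among the other genes that rose most, the uncharacterised gene 1110032F04Rik was below background in all 6 control arrays and at least 25.8-fold higher with POU4F1 (9.16 ± 0.80, SD, n = 3, against a measured 3.44 ± 0.09, n = 6). The tetraspanin gene Tspan12, the scaffold gene Tanc1 and Sptssb, a subunit gene of serine palmitoyltransferase, were also below background in the controls and rose at least 4.79-fold, 11.5-fold and 3.43-fold. Such bounds set the control arrays at the higher of their value and the array's 40th percentile. Diras2, a small GTPase gene of the Ras family, rose 16.6-fold, with 5 of the 6 control arrays above background. Rprm, known as a p53-induced arrest gene, rose 9.17-fold, and Rps6ka6, a ribosomal S6 kinase gene, rose at least 5.17-fold, with 2 of the 6 control arrays above background. Socs2, a feedback inhibitor of cytokine signalling, rose 6.89-fold from 8.31 ± 0.42 to 11.09 ± 0.16, and Parm1 rose 6.54-fold. Limma's adjusted p of these 9 genes lay between 4.20e-05 for Tspan12 and 0.0384 for Rps6ka6. A second probe set of 1110032F04Rik and of Diras2 differed by only -0.14 each on the log2 scale, that of Cav2 by 0.60 and that of Rps6ka6 by 0.92. The 3 other probe sets of Socs2 ran from -0.03 to 3.38, with 1 called, while that of Parm1 was called at 2.63. Different probe sets of a gene thus did not always read the same change. Of 50 called genes with several tested probe sets, 39 had all of them changing in the same direction.

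The 12 named genes that fell changed less, by 2.31-fold to 4.93-fold. Trgv4, a variable segment of the T cell receptor gamma locus, fell by 2.30 on the log2 scale (adjusted p = 8.32e-04), but its probes may also read related gamma segments. Cma1, the mast cell chymase, fell 3.69-fold from 9.33 ± 0.18 (SD, n = 6) to 7.45 ± 0.38 (n = 3; limma adjusted p = 0.00409). Mcpt8, a basophil protease, fell 2.59-fold from 10.57 ± 0.20 to 9.19 ± 0.14 (adjusted p = 0.00689), and Nkg7, a granule gene of cytotoxic cells, fell 2.48-fold from 11.39 ± 0.16 to 10.08 ± 0.13 (adjusted p = 0.00487). The macrophage lectin gene Mgl2 fell 2.59-fold, the glypican gene Gpc1 2.57-fold, the potassium channel gene Kcnk12 2.35-fold, the NF-kB scaffold gene Card10 2.31-fold and the growth factor gene Fgf3 2.31-fold. Slc45a3, Selenom and Tmem53 fell 2.75-fold, 2.61-fold and 2.59-fold. Adjusted p of these 8 genes lay between 0.0224 for Card10 and 0.0484 for Mgl2. Over all 13916 genes the 3 POU4F1 arrays lay entirely above or below the 6 control arrays in 6.58%, where chance gives 2.38%, and genes were named only if they did.

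Leaving out single arrays ended the call of 10 of the named genes. Rps6ka6, Selenom and Tmem53 then passed only without wild-type control 3, Mgl2 only without wild-type control 2, and Gpc1, Kcnk12 and Fgf3 only without wild-type control 1 or 3. Card10 passed only without wild-type control 1 or 3 or knockout control 3, Slc45a3 only without wild-type control 1 or 3 or POU4F1 array 3, and Mcpt8 was lost without POU4F1 array 1 (0.0512) or 2 (0.0632). Without POU4F1 array 2 limma's adjusted p was 0.229 for Rps6ka6, 0.254 for Selenom and Fgf3, 0.195 for Tmem53 and Kcnk12, 0.219 for Mgl2, 0.153 for Gpc1, 0.130 for Card10 and 0.168 for Slc45a3. The other 14 named genes, Cav1, Thy1 and Cma1 among them, passed without each array in turn. Over 22 settings of the fit Cma1 and Nkg7 each kept the call in 21, with limma's adjusted p up to 0.121 and 0.134. Cav1 and Thy1 kept it in 22.

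**Figure D1:**
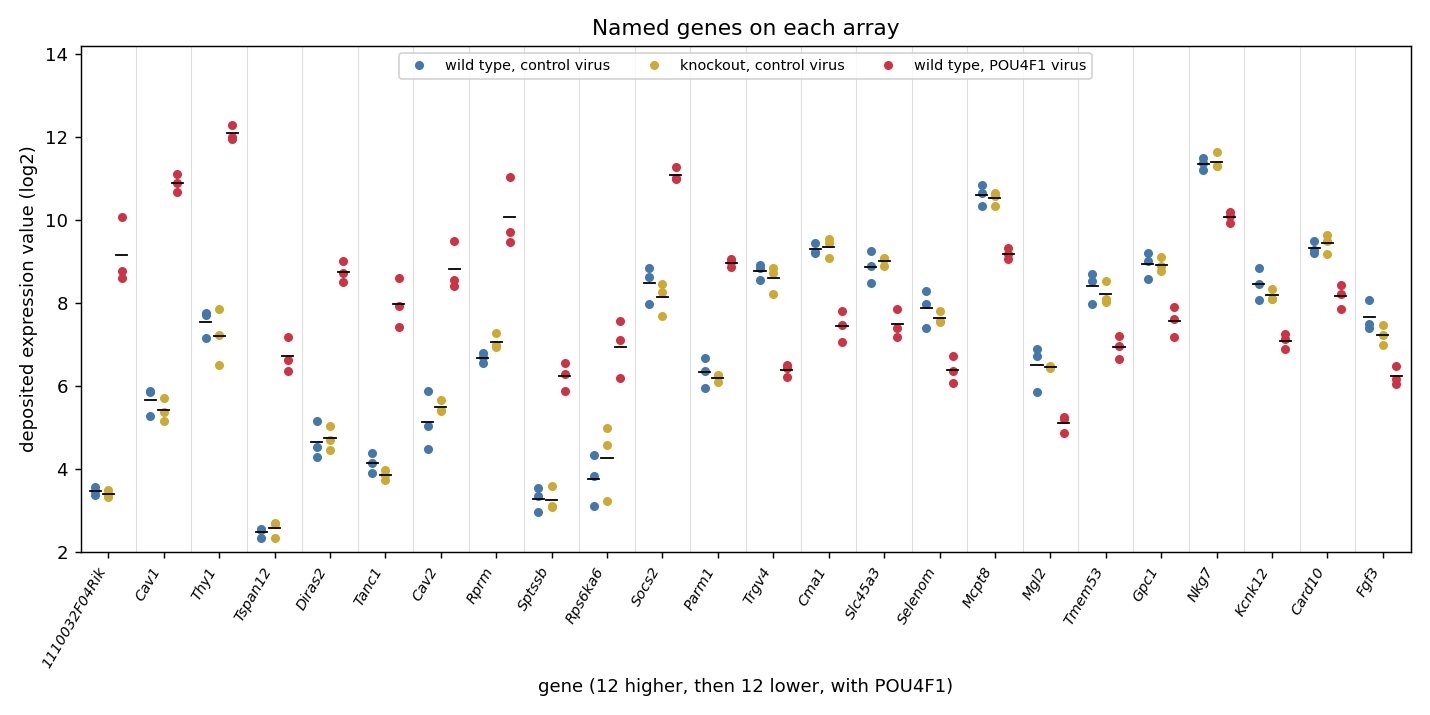
The plot gives the deposited log2 value (vertical axis) of each array as a point for the 12 higher and 12 lower named genes (horizontal axis), with a short black line at each group's mean. The 3 POU4F1 arrays lie above all 6 control arrays for the first 12 genes, for example 10.89 against 5.55 on average for Cav1, and below them for the last 12, as the choice of genes required.

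The description of the series states 140 differentially expressed genes, with neither test nor threshold given in the sources used here. The count of 123 depended on single arrays. It was 67 without wild-type control 2, 68 without knockout control 2, 68 without knockout control 3, 62 without POU4F1 array 1 and 56 without POU4F1 array 2, and 1218 with array weights. A preparation code in the labels splits the arrays into 6 and 3. With that code as a block the count was 191 (142 higher and 49 lower). It was 37 (34 higher and 3 lower) within the 6 arrays of the first preparation, 2 per group. The second preparation held 1 array per group and allowed no test, but all 123 probe sets kept their sign there, against 73.3% of all probe sets, in arrays that also entered the fit.

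Cell type lists fixed beforehand were lower for 3 granulocyte and platelet lineages. Of 17 tested mast cell, basophil and eosinophil genes, 15 were lower with POU4F1 (median log2 change -0.51, camera adjusted p = 6.60e-05). The call was lost with an estimated correlation, with an adjusted p = 0.218, while the rotation test fry gave an adjusted p = 0.0147. Over all probe sets 2 passed, Cma1 and Mcpt8, and adjusted over the list alone 4 passed as lower and 1 as higher. Besides Cma1 and Mcpt8, those were the mast cell tryptase gene Tpsb2 (log2 change -0.68 ± 0.18, SE) and the eosinophil peroxidase gene Epx (-1.42 ± 0.42) as lower and the prostaglandin D synthase gene Hpgds (1.32 ± 0.27, with 3 of the 6 control arrays above background) as higher. Within the first preparation 14 of the 17 were lower and camera's adjusted p was 1.145e-04, and in the second preparation, without a test, 16 were lower.

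**Figure D2:**
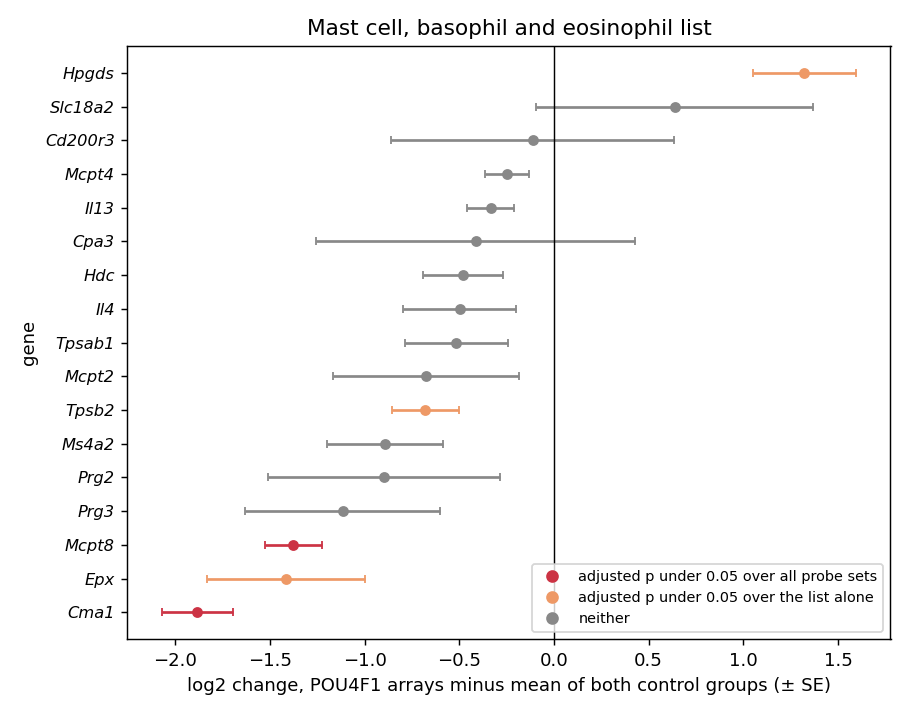
Each point is the log2 change (horizontal axis) of 1 gene of the mast cell, basophil and eosinophil list (vertical axis), POU4F1 arrays minus the mean of both control groups, with a bar of 1 SE, coloured by whether it passed over all probe sets, over the list alone or neither. Of the 17 genes 15 lie below 0, from -1.88 for Cma1, and Hpgds lies highest at 1.32.

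The neutrophil list was lower as well, with 18 of 23 genes below 0, a median log2 change of -0.40 and a camera adjusted p = 0.0143. This call was lost with an estimated correlation, at adjusted p = 0.758. No member passed over all probe sets. Adjusted over the list alone, the ficolin gene Fcnb (-1.78 ± 0.45, SE) and Gfi1 (-0.83 ± 0.20), a repressor needed for neutrophil formation, passed as lower, and the chitinase-like gene Chil3 (1.68 ± 0.41) passed as higher. The granule gene Ms4a3 differed by -0.54 ± 0.20 and did not pass. The megakaryocyte list had 14 of 17 genes below 0, a median of -0.27 and a camera adjusted p = 0.0438, and this call was lost as well, at adjusted p = 0.707. The platelet glycoprotein genes Gp1bb (-1.02 ± 0.23), Gp9 (-0.60 ± 0.17) and Gp5 (-0.64 ± 0.18) passed as lower adjusted over the list alone, and none over all probe sets, while Selp (-1.06 ± 0.35) passed neither. Without POU4F1 array 3 both had a camera adjusted p of 0.318. Without wild-type control 2 or knockout control 1 the neutrophil list had 0.0657 and 0.111, and the megakaryocyte list had 0.0823 and 0.128. The megakaryocyte list also missed the threshold without wild-type control 3 (0.0667).

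Of 13 tested genes known to be high in leukaemia with the RUNX1-RUNX1T1 fusion, 5 were higher and 8 lower with POU4F1, and the list did not pass camera (adjusted p = 0.656, median -0.06, mean 0.36). Cav1 passed over all probe sets. Adjusted over the list alone, 2 passed as higher, Cav1 and Hpgds, and 1 as lower, Baiap3 (-1.20 ± 0.24, SE), while Palm (-0.61 ± 0.23) did not pass. Of 21 stem and progenitor genes 10 were higher and 11 lower (camera adjusted p = 0.319, median -0.00, mean 0.08). Mecom, a transcription factor gene of blood stem cells, rose at least 1.63-fold, with 2 of the 6 control arrays above background (limma adjusted p = 0.0327). Mecom lost its call without wild-type control 2 (0.111) or 3 (0.0604), knockout control 2 (0.0979) or 3 (0.115), or POU4F1 array 1 (0.182), 2 (0.102) or 3 (0.138). Adjusted over the list alone, 2 passed as higher, Mecom and Hlf (0.71 ± 0.15), and 1 as lower, Mycn (-0.45 ± 0.11), while Slamf1 (-0.91 ± 0.29) did not pass. The endothelial and stromal list, markers of other fetal liver cells, had 12 of 13 genes below 0 (median -0.30, camera adjusted p = 0.0591), and the hepatocyte list 10 of 13 (median -0.17, camera adjusted p = 0.137). No member of either passed over all probe sets or over the list alone.

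The comparison with wild-type controls alone held the genotype fixed, so that the virus differed. Cav1 rose 37.1-fold, Thy1 23.4-fold and Diras2 17.1-fold (2 of 3 wild-type arrays above background), 1110032F04Rik at least 25.4-fold and Tspan12 at least 4.71-fold, with limma adjusted p between 6.20e-05 and 0.00108. Trgv4, Cma1, Mcpt8, Kcnk12 and Nkg7 fell 5.25-fold, 3.61-fold, 2.67-fold, 2.59-fold and 2.44-fold, with adjusted p between 0.00209 and 0.0454. Of these, Trgv4 alone passed without each array in turn. Without wild-type control 2 the adjusted p of Cma1, Mcpt8, Kcnk12 and Nkg7 was 0.0706, 0.105, 0.204 and 0.103, and without POU4F1 array 2 it lay between 0.0764 for Cma1 and 0.232 for Kcnk12. Nkg7 was also lost without wild-type control 1 (0.0550) and POU4F1 arrays 1 (0.0636) and 3 (0.0581), Mcpt8 without POU4F1 array 1 (0.0879), and Kcnk12 without any array but wild-type control 3 (0.0872 to 0.232). In all, 79 probe sets passed, 68 higher and 11 lower. Of the lists only the mast cell, basophil and eosinophil list passed, with 13 of 17 genes below 0 (camera adjusted p = 0.00583, and adjusted p = 0.601 with an estimated correlation), and without wild-type control 3 it had 0.111. The count was 52 without wild-type control 1, 26 without wild-type control 2, 39 without POU4F1 array 1 and 36 without POU4F1 array 2, and 23 when fitted on these 6 arrays alone. It was 140 with the preparation code as a block, 19 within the first preparation and 7090 with array weights. With the preparation mark as a block it was 58, of which 54 were higher and 4 lower, and 49 were shared with the main fit. That block also spanned the knockout controls, and no fit paired by mark within these 6 arrays alone is given.

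Against the knockout controls, where virus and genotype both differed, 70 probe sets passed, 61 higher and 9 lower. Cav1 rose 44.4-fold, Thy1 29.6-fold, 1110032F04Rik at least 26.3-fold, Tanc1 at least 11.7-fold and Tspan12 at least 4.87-fold, with limma adjusted p between 4.10e-05 and 6.48e-04. Trgv4, Cma1, Nkg7 and Mcpt8 fell 4.63-fold, 3.76-fold, 2.52-fold and 2.52-fold, and Padi2, a peptidylarginine deiminase gene, fell 2.28-fold, with adjusted p between 0.00301 and 0.0238. Without POU4F1 array 2 the adjusted p of Cma1, Nkg7, Mcpt8 and Padi2 was 0.0722, 0.0884, 0.145 and 0.0722, and without knockout control 3 it was 0.0838, 0.0833, 0.143 and 0.1003. Cma1 was also lost without knockout control 2 (0.0780), Nkg7, Mcpt8 and Padi2 without knockout controls 1 and 2 and POU4F1 arrays 1 and 3, and Mcpt8 without wild-type control 2 (0.0672). The mast cell, neutrophil and megakaryocyte lists were lower (camera adjusted p = 8.11e-07, 1.87e-04 and 7.87e-04), as were the inflammatory cytokine list (0.0377) and the endothelial and stromal list (0.0495), and the Hoxa and Meis list was higher (0.0495). All these calls were lost with an estimated correlation, where the smallest adjusted p = 0.103. Only the mast cell list passed fry (adjusted p = 0.0383). The count was 42 without wild-type control 2, 32, 29 and 27 without knockout controls 1, 2 and 3, and 37 and 34 without POU4F1 arrays 1 and 2, and it was 16 within the first preparation and 394 with array weights. Without POU4F1 array 3 the neutrophil and megakaryocyte lists had a camera adjusted p of 0.122 and 0.1002. The inflammatory list was lost without wild-type control 1 (0.0685), knockout controls 2 (0.0626) and 3 (0.0511) and POU4F1 arrays 1 (0.0503), 2 (0.0614) and 3 (0.0810). The endothelial and stromal list was lost without wild-type control 1 (0.0686), knockout controls 2 (0.286) and 3 (0.0760) and POU4F1 arrays 1 (0.0534) and 3 (0.196). The Hoxa and Meis list was lost without knockout controls 1 (0.186), 2 (0.0626) and 3 (0.0511) and POU4F1 arrays 1 (0.0503), 2 (0.0607) and 3 (0.190).

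Of the probe sets called against each control, 51 were higher and 9 lower against both. These comparisons share the POU4F1 arrays. Simulated unchanged groups with shared arrays gave an overlap of 0.01 on average and at most 1. With no changed probe sets few calls can arise there, so this does not show how much overlap the shared arrays add. Independent lists of these lengths would share 0.148 higher and 0.00354 lower probe sets. Part of the overlap may come from the shared arrays, which are too few to split.

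The last comparison set knockout against wild-type cells, both with the control virus, to show what the loss of Pou4f1 changes. No probe set passed in limma, the smallest adjusted p was 0.838 (0 under 0.1), while array weights, which put a weight of 70.4 on wild-type control 2 and at most 2.83 on the others, called 5661 (2648 higher and 3013 lower). In the fit without weights 594 probe sets had an unadjusted p under 0.05, where 1400 would be expected by chance alone. The genes with the smallest p were Klhl2 (log2 difference 1.00 ± 0.23, SE), Gucy1b1 (at least 1.43-fold, below background in wild-type cells) and Lrrk2 (0.78 ± 0.20) on the higher side and Kcnj1 (at least 1.45-fold, above background in 1 of 3 knockout arrays), Gm13648 (-0.54 ± 0.14) and Stk38l (at least 1.35-fold, below background in knockout cells) on the lower side, and none of them passed. In data simulated with the spread of these arrays and independent probe sets, this comparison recovered 21% of 2-fold and 77.3% of 4-fold changes. POU4F1 against both controls recovered 42.6% and 82.4%. Of 21 stem and progenitor genes 16 were higher in the knockout (median 0.14, camera adjusted p = 0.0279), but the list had an adjusted p = 0.781 with an estimated correlation and 0.956 in fry. Its members Slamf1 (0.62 ± 0.34, SE), Kit (0.71 ± 0.39), Mecom (at least 1.01-fold, below background in wild-type controls) and Erg (0.61 ± 0.36) had the smallest p, and 0 of the 21 passed over all probe sets or adjusted over the list alone. Without wild-type control 1, wild-type control 2 or knockout control 1 the list's camera adjusted p was 0.241, 0.113 and 0.166. Within 20 Mb of Pou4f1 on its chromosome, 0 of 79 probe sets passed, and 2 of them (2.53%) had an unadjusted p under 0.05 against 2.08% elsewhere (Fisher's exact test, two-sided, p = 0.681).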

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

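The tests of splits, of RNA integrity and of the preparations in the higher probe sets, of endothelial cells, of an equal fall of all mast cell list members and of the recovery of 2-fold and 4-fold changes in the knockout comparison were chosen after results had been seen. Outside the probe sets that passed the filter, 10 probe sets passed an adjusted p of 0.05 for POU4F1 against both controls in a limma fit of all probe sets. They stood out as a signal in data the report does not use, and all 10 read higher with POU4F1 and lay below background in all 6 control arrays. Robo1, an axon guidance receptor gene of the leukaemia list (adjusted p = 0.00468), and Insm1 stayed below background on the POU4F1 arrays as well, so no fold is given. Mab21l1, 2 probe sets of Ppargc1a, a regulator of mitochondrial genes, and 1 probe set unnamed here had POU4F1 means too low for a bound. Adgrd1, Edil3, Sntb1 and Dclk3 were at least 1.24-fold, 1.23-fold, 1.19-fold and 1.05-fold higher, each with 2 of 3 POU4F1 arrays above background.

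The first pattern is the 99 probe sets that were higher with POU4F1. The 9 arrays were split into 3 and 6 in a fit of 2 groups. Of the 84 splits, 3 called as many probe sets higher as the real split, itself included. The real split called 127, and splits that mix the groups called 309 and 128. For both directions together it was also 3 splits, with 164 for the real split and 854 for the highest other. Because mixed splits called more than the real one, and arrays share preparation marks, the splits do not exclude chance. The 309 came from wild-type control 3, knockout control 1 and POU4F1 array 3 set apart and the 854 from wild-type controls 1 and 2 and knockout control 2, which points to a structure of the arrays besides the groups (the split by preparation code called 47 in both directions, and the first principal component, 54.5% of the variance, ran from -114 for wild-type control 1 to 69.8 for POU4F1 array 3). The Gapdh value differed little between groups, at -3.71 ± 0.84 (SD, n = 3) with POU4F1 against -3.80 ± 1.94 and -3.34 ± 0.11 in wild-type and knockout controls. With that value as a covariate, 99 of the 99 probe sets kept their log2 change within 20%. Near-equal groups leave a covariate little to shift, so only unequal mean integrity between the groups is argued against. Endothelial or stromal cells, which express caveolin and Thy1, are argued against by a mean log2 change of -0.21 ± 0.12 (SE) over their list, of which the brightest were Egfl7 (9.32 in controls, 8.95 with POU4F1) and Acta2 (8.28 and 7.91), in cells sorted for GFP. A rise in the first preparation only is argued against for the 34 probe sets called higher in that preparation alone, of which 33 kept at least 50% of the change in the second, against 0.607 expected if they read there like all probe sets (this reading was set after the value was seen), while for 67 of the 99, which were not called there, it stays open beside a response of the cells to the POU4F1 virus.

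The second pattern is the lower mast cell, basophil and eosinophil list. With the Gapdh value as a covariate its mean log2 change was -0.58, against -0.56 without it. As above, this argues only against unequal mean RNA integrity between the groups. An equal fall of all members is argued against by the 8 members with a control mean above 8, which ranged from -0.41 to -1.88. The -0.41 was that of Cpa3 and rests partly on 1 array. Cpa3 read 6.91 on wild-type control 1 and 10.17 to 11.36 on the other control arrays. Cd200r3, a dimmer member, also read low there (3.61 against 6.22 to 7.43), while Hdc (12.67) and Epx (10.73) did not. Cochran's Q of the 8 members was 28.6, with a chi-square p of 1.72e-04 that treats members as independent. A smaller share of these cells would give an equal fall only if no other cells expressed these genes and all probe sets responded alike. Unequal falls therefore do not exclude a smaller share of all these cells together. A change in the share of mast cells, basophils or eosinophils alone, or a change within these cells, may also remain and was not tested.

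For the third pattern, the absence of calls between knockout and wild-type controls, 21% of 2-fold changes were recovered in simulated data, so too few arrays may account for missing changes of that size. Of 4-fold changes 77.3% were recovered, which excludes nothing about real cells, since it rests on simulated settings, and this reading was set after the value was seen. Wild-type and knockout controls make 10 splits, too few for a share under 0.05, and the real split called 0 and the highest other 291, again with wild-type controls 1 and 2 and knockout control 2 on the same side, while all 10 splits called at least as many as the real split. Array weights called 5661, with a weight of 70.4 on wild-type control 2. Gene-by-gene weights, with 5.29 on that array, called 0, so the absence of calls held with equal weights and with 1 of the 2 kinds of unequal weights. Whether fetal liver cells express Pou4f1 stays open, since both of its probe sets lay below background on all arrays.

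For POU4F1 against wild-type controls and against knockout controls the 10 splits are also too few, with 23 and 47 called by the real splits, each of which was the 1 split with as many, and 0 by the highest other.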

How the results depend on the processing

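The Gapdh covariate, the gene-by-gene weights, the fit without the 2 outermost arrays and the fit of the first preparation were chosen after seeing the data. For the counts, in the order POU4F1 against both controls, wild-type controls and knockout controls, array weights gave 1218, 7090 and 394 (and 5661 for knockout against wild-type), with a weight of 70.4 on wild-type control 2 and at most 2.83 elsewhere, and gene-by-gene weights gave 700, 1179 and 301. An adjusted p under 0.1 gave 198 and 149 for the first and second, the preparation code as a block 191 and 140, and the Gapdh covariate 236 and 240. The first preparation alone gave 37, 19 and 16, from fewer arrays. Against wild-type controls the 6 arrays alone gave 23 and the fit without the outermost arrays 43. Leaving out each array gave 56 to 129, 26 to 79 and 27 to 81. Knockout against wild-type stayed at 0 in all but the array weights, and so did probe sets near Pou4f1 at 10 and 40 Mb. The replicate block by preparation mark moved the counts to 103, 58 and 42. Of the 103, 84 were higher and 19 lower, and 84 were shared with the main fit. Under this block 71 of the 99 higher probe sets of the main fit were still called. Of the 58, 54 were higher and 4 lower, with 49 shared. Of the 42, 38 were higher and 4 lower, with 41 shared. Arrays of equal mark did not all deviate together, as 4 of 9 correlations of deviations exceeded 0.1. They ran from -0.36 to 0.28 between the control groups, from 0.07 to 0.56 between wild-type controls and POU4F1 arrays and from -0.55 to 0.16 between knockout controls and POU4F1 arrays. As a hint from the data, 3 of 3 wild-type controls correlated best with the POU4F1 array of their own mark, and 2 of 3 POU4F1 arrays with the wild-type control of theirs. Pou4f1's log2 change was 0.00278 with array weights and 0.05 to 0.17 without each array.

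Camera's adjusted p of the mast cell list for POU4F1 against both controls was 0.218 with an estimated correlation and passed elsewhere. The neutrophil list had 0.183 with array weights, 0.163 with gene-by-gene weights, 0.758 with an estimated correlation, 0.407 in fry, 0.406 without the outermost arrays and 7.66e-05 to 0.318 without each array. The megakaryocyte list had, in that order, 0.388, 0.338, 0.707, 0.369 and 0.352, with 0.0549 under trended variances, 0.0648 with the Gapdh covariate, 0.104 in the first preparation and 0.00104 to 0.318 without each array. The stem and progenitor list in the knockout had 0.366 with the stricter filter, 0.0602 after quantile normalization, 0.0720 and 0.0889 with the 2 kinds of weights, 0.781 with an estimated correlation, 0.956 in fry, 0.0912 with the most variable probe sets, 0.276 without the outermost arrays and 0.0154 to 0.241 without each array. The cause was not tested. For named genes and list members in POU4F1 against both controls, 152 values under the alternatives lost a call and 48 gained one, and no called value changed sign. Against wild-type and knockout controls 33 and 32 lost it. Signal near background limits the changes that can be read, since 22 of the 123 called probe sets lay below the 40th percentile in all control arrays.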

Other observations

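The hypothesis on neighbouring genes and its test, and the test of genes above background in the knockout, were chosen after the result was seen. In other lists, none of which passed camera for POU4F1 against both controls, single members stood out. Avil (advillin), an actin-binding protein gene of sensory neurons, rose by 2.07 ± 0.27 (SE) from 6.97 to 9.05 (limma adjusted p = 0.0164), while 14 of 16 sensory neuron genes lay below 0 (camera adjusted p = 0.206) and adjusted over the list alone Avil was the 1 to pass. Bmf, a pro-apoptotic gene, rose by 1.56 ± 0.20 (adjusted p = 0.0155), with 7 of 14 genes of the BCL-2 family higher (camera adjusted p = 0.907). Jun rose by 1.24 ± 0.20 (adjusted p = 0.0472), with 10 of 18 immediate early and stress genes higher (0.140). Clec7a, the receptor dectin-1 of myeloid cells, rose by 2.11 ± 0.34 (adjusted p = 0.0429), with 17 of 25 monocyte and macrophage genes below 0 (0.907). Among 13 T and NK cell genes Thy1 rose and Nkg7 fell, and 11 were below 0 (0.446, median -0.11, mean 0.13). Adjusted over the list alone, Irf8 (1.05 ± 0.22) also passed among monocyte genes, and Gzmb (-0.93 ± 0.21) among T and NK cell genes. Medians and means of the monocyte list (-0.10 and 0.05) and the BCL-2 list (-0.05 and 0.10) differed in sign. Jun and Clec7a were lost without any array but wild-type control 1, up to an adjusted p of 0.212 and 0.229. Avil was lost without knockout control 1 (0.0532) or 2 (0.0569) or POU4F1 array 1 (0.0974), 2 (0.116) or 3 (0.0690). Bmf was lost without knockout control 1 (0.0501) or 3 (0.0536) or POU4F1 array 1 (0.0945) or 2 (0.110), and the mean of its probe sets gave 0.42 (adjusted p = 0.426).

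No member passed over all probe sets in the lists of Hoxa and Meis genes (4 of 6 higher, camera adjusted p = 0.137), erythroid genes (9 of 25 higher, 0.894), B cell genes (2 of 11 higher, 0.124), dendritic and MHC class II genes (3 of 17 higher, 0.124), cell cycle genes (14 of 31 higher, 0.939), interferon response genes (10 of 19 higher, 0.503), p53 targets (10 of 18 higher, 0.714), inflammatory cytokines (6 of 18 higher, 0.113), unfolded protein and ATF4 targets (5 of 18 higher, 0.137) and cholesterol synthesis genes (7 of 14 higher, 0.895). The cell cycle list had a median of -0.05 and a mean of -0.04 although camera ranked it upward, and the cholesterol list a median of -0.00 and a mean of 0.05. Adjusted over the list alone, the chemokine genes Ccl4 (-0.89 ± 0.19) and Ccl9 (-0.71 ± 0.19) passed as lower among inflammatory cytokines. Another 14 genes passed on a probe set other than their brightest and are named here after their values were seen. They include the carboxypeptidase gene Cpe (at least 8.79-fold higher), the apelin receptor gene Aplnr (at least 19.0-fold higher, with 2 of the 6 control arrays above background) and the actin regulator gene Coro2b (at least 11.2-fold higher), with limma adjusted p of 4.20e-05, 4.20e-05 and 7.66e-06. The brightest probe sets of these genes differed by -0.03, 0.28 and 0.32. Of the probe sets without a gene name, the one with the largest rise was at least 16.4-fold higher with POU4F1 (adjusted p = 3.83e-04).

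In the sex-linked check list, the Y-linked Eif2s3y read between 6.86 and 8.20 on wild-type control 3, knockout controls 2 and 3 and POU4F1 array 3, and between 2.97 and 3.35 on the other 5 arrays, and no group comparison of the list passed. By Eif2s3y, the wild-type control and POU4F1 arrays of the same preparation mark fell on the same side for all 3 marks. The other probe set of Eif2s3y, and those of Kdm5d and Uty, read below background on every array. The brightest probe set of Xist read between 8.82 and 11.19 on all 9 arrays, those with high Eif2s3y included. The list therefore does not divide the arrays cleanly by sex.

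A first hypothesis was that loss of Pou4f1 moves the genes called with the virus the opposite way. The 65 higher genes differed by 0.077 ± 0.053 (SE over genes) on the log2 scale between knockout and wild-type controls. Of these genes 36 were higher and 29 lower in the knockout, and the 18 lower genes differed by -0.10 ± 0.08. Of the 65, 24 lay too near background in wild-type controls to show a drop of 1.5-fold, so their mean decides nothing about them. The other 41 differed by 0.076 ± 0.063 (SE over genes), with 21 higher and 20 lower, so their mean showed no drop on these arrays. That SE does not measure the spread between arrays, so it excludes neither a mean drop of 1.5-fold nor smaller shifts. A second hypothesis was that called genes lie next to each other on the chromosome more often than random genes, as Cav1 and Cav2 do. Of 83 called genes 3 neighbouring pairs were called together, against 0.494 on average in 10000 random draws (permutation p = 0.0146). The pairs were Cav2 with Cav1, Cblb with Alcam, and Gpr137b with its copy Gpr137b-ps, whose probes may read both genes. Without the copies 2 pairs were left and the permutation p was 0.0886. The pair of Cav2 and Cav1, with which the hypothesis was put, counts in both results. Neither p is therefore an independent test, and the data do not settle the hypothesis.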
